A study of Drosophila melanogaster with 2 samples.

How the data were processed

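Anti-GFP ChIP-seq of Spps-GFP was carried out on whole Drosophila melanogaster embryos of 0 to 12 h, in 2 biological replicates of 1 group, with chromatin sonicated and a size range of 200 to 800 bp per the labels. The labels name the 2 samples as separate biological replicates.

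The deposited peak lists are on dm6 per the labels. The aligner, peak caller, IDR threshold and filters are not given in the sources used here. Per the file headers and listings that accompany the samples, each replicate list was derived from that replicate's alignment, a further list from both alignments together, and the IDR list from these, with the same 1 control for both replicates. The signal of a peak is the deposited value of the authors' caller, relative to the control, on a linear scale that differs between lists, and it was used only to rank, filter or describe peaks within a list, or as log2 signal between matched replicate peaks. The deposited −log10 q-value was the same for all 3260 IDR peaks (3.96) and was not used to rank. The summit offset is the deposited distance from peak start to summit. Coordinates were converted to 1-based positions. The 3 lists with 30000 peaks stop at that number, so a missing peak is not an absence of binding.

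All 3260 IDR peaks were the 3260 highest-signal peaks of the pooled list, with the same summits, so a pooled list of that length is the same set of peaks and changes nothing. Peaks lay on 6 arms (2L, 2R, 3L, 3R, 4 and X). Genes, transcripts and exons came from Ensembl release 115 (BDGP 6.54), without transposable elements, and sequence from RefSeq assembly release 6, which has the coordinates of dm6. There were 13968 protein-coding genes on the assembled chromosomes. The 19 gene lists gave 833 symbols, of which 825 matched the annotation and were used.

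A promoter was the 500 bp to either side of any annotated TSS, and a distal summit lay over 2 kb from any. Promoter took precedence over exon, exon over intron, and intron over intergenic sequence. Shares of summits per class and arm were tested by exact binomial tests, gene lists, divergent promoters and promoter motifs by two-sided Fisher's exact tests, and motifs at summits by exact McNemar tests against a flank 500 bp to a randomly drawn side. Benjamini-Hochberg adjustment ran over the members of each family, with a threshold of 0.05. Exact (Clopper-Pearson) 95% intervals are given for shares, and the limit that a count of 0 allows is 3 counts. A fold against a control count of 0 used 3 counts. Hox complexes were compared with 10000 random windows, list signals with 10000 random sets of bound genes, and replicate overlap with 1000 circular shifts. Motifs were searched as consensus strings on both strands within 100 bp of a summit or 200 bp of a TSS. Peaks and genes are not replicates, and no test compares samples.

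Gene lists, motifs, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule named the 20 highest-signal IDR peaks with a summit within 500 bp of a protein-coding TSS by nearest gene, all Hox genes, en, inv, ph-p, ph-d and Spps, the 3 members of each list with the strongest promoter peak, and the 5 strongest peaks over 2 kb from a TSS. Of the genes this rule named, 1 is not reported here. Other genes were named after their values were seen: Psc and Pc among locus-level members, bxd and Ama in the Hox complexes, and CG12096, arg and ush as genes that hold named summits. Alternatives were the 1000 strongest IDR peaks, each replicate alone, other windows, other assignments of peaks to genes, other backgrounds and controls, and, chosen after the data were seen, 2 combinations of these and the outermost TSS of every gene for promoter motifs.

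The tests were checked on simulated data. In simulated gene lists of 40 genes, 6% of 200 random lists were called at an unadjusted threshold, 51.5% of lists with a bound share 2 times that of all genes and 100% with 4 times. In the genomic distribution test 8% of 50 sets of uniform summits were called and 100% of sets with 10% of summits moved to promoters. In the motif test 4% of 50 sets without added sites were called and 100% with sites added to 5% of windows. In the Hox complex test 6% of 50 uniform sets were called and 100% with 3 times the summits. In the data, most random windows of the bithorax complex's length held 0 to 20 summits, around a mean of 7.78. The uniform sets were not matched to that spread, so the Hox complex rates need not hold for the data. Scripts ran in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The text listings of files were not used for values.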

Results

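The data were ChIP-seq peak lists for Spps (Sp1-like factor for pairing sensitive-silencing), a zinc finger protein of the Sp/KLF family known to act at Polycomb response elements. Spps carried GFP at its C-terminal end in a transgenic fly line, and its chromatin was recovered with an anti-GFP antibody from whole embryos aged 0 to 12 h. There were 2 biological replicates of 1 group, so the design held no contrast between conditions. Each replicate list held 30000 peaks, as did the list called on both replicates together, and the thresholded list of reproducible peaks (IDR, irreproducible discovery rate) held 3260. The lists give no read counts, so the depth of each library is unknown, and intervals below cover counting over peaks or genes only.

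The replicates placed most of their strongest peaks at the same sites. Of the 3260 highest-signal peaks of replicate 1, 2455 (75.3%, exact 95% interval 73.8 to 76.8) had a summit of the replicate 2 list of equal length within 200 bp, and 2483 (76.2%, 74.7 to 77.6) did in the reverse direction. After circular shifts of one list along each chromosome arm, the mean share was 0.972% and the highest of 1000 shifts 1.66% for replicate 1. The strongest peak of both replicates lay at px (plexus), a gene named for its wing vein phenotype, with a signal of 1078 in replicate 1 and 702 in replicate 2.

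Signal also ranked alike between the replicates. Among 3251 IDR peaks matched in both lists, log2 peak signal correlated with Pearson r = 0.817 and Spearman rho = 0.749, a description across peaks, which are not independent replicates. The IDR peaks were the highest-signal peaks of the pooled list, which both replicates feed. Both replicates were also called against the same control, so part of the agreement follows from the construction. Of the IDR peaks, 2 were missing from the full list of replicate 1 and 7 from that of replicate 2.

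**Figure D1:**
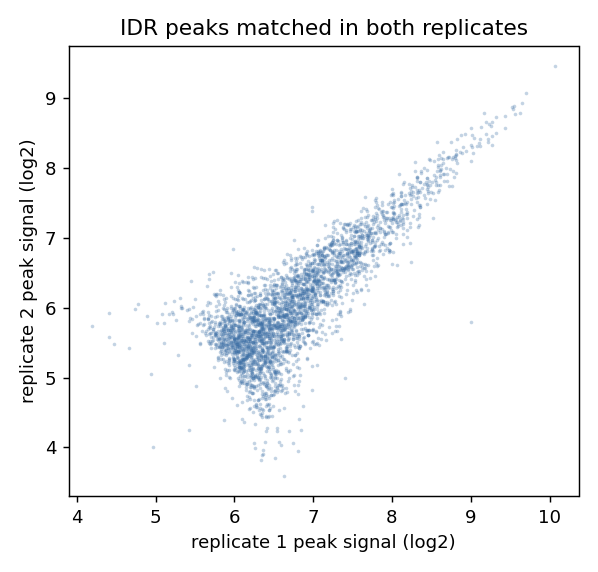
Each point is 1 of the 3251 IDR peaks matched in both replicates, with its replicate 1 signal on the x axis and its replicate 2 signal on the y axis, both as log2 of the caller's signal value. The points run along a diagonal with r = 0.817.

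Spps-GFP summits lay at promoters far more often than the genome's composition gives. Promoters, the 500 bp to either side of an annotated transcription start site (TSS), held 1492 of 3260 summits (45.8%, exact 95% interval 44.0 to 47.5) and 13.6% of the chromosome arms, a 3.37-fold excess. Exons held 89 summits (2.73%) against 19.8% of sequence, 0.138 of the share of sequence. Introns held 1155 (35.4% against 39.5%) and intergenic sequence 524 (16.1% against 27.1%). Each class differed from its share of sequence in exact binomial tests with Benjamini-Hochberg adjustment over the 4 classes, with an adjusted p of 1.7e-06 for introns, the class closest to its share, and 1.8e-190 for exons. Against 1000 circular shifts the promoter excess was 3.36-fold, with permutation p = 0.002, the smallest that the shifts can give. With a promoter window of 250 bp the intron share no longer passed (exact adjusted p = 0.29), and with protein-coding transcripts alone exons stood at 0.0811 of their share.

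**Figure D2:**
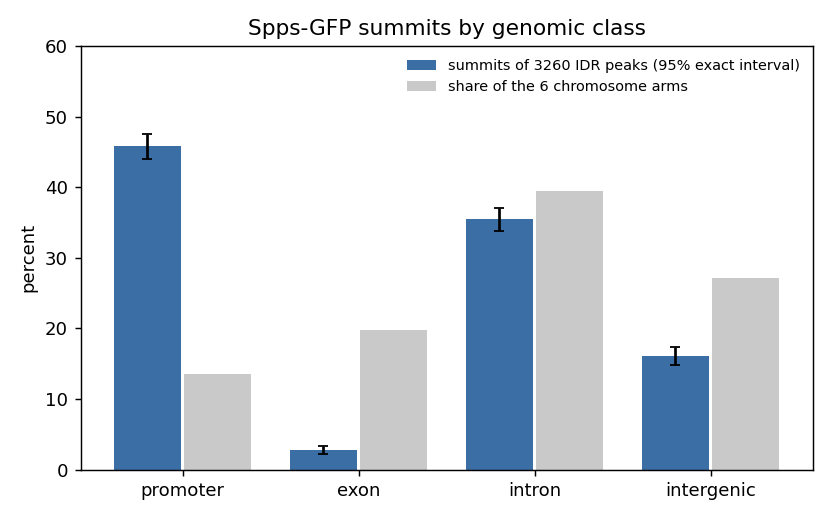
Bars show the percent of the 3260 IDR summits in each genomic class, with exact 95% intervals, beside the percent of the 6 chromosome arms in that class. Promoters reach 45.8% against 13.6%, while exons stand at 2.73% against 19.8%.

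Near promoters the summits sat on the upstream side. Of the summits within 500 bp of a TSS, 1193 lay upstream and 298 downstream (80.0% upstream, 77.9 to 82.0, exact binomial p = 8.1e-127), with a median summit position of -112.5 bp relative to the TSS. Over all IDR peaks the median distance to a TSS was 683 bp, and 1060 peaks lay over 2 kb from any TSS. The strongest of these distal peaks was intergenic, at chromosome 2L 2202224 to 2202581 (dm6), 3756 bp from the TSS of CG31668, with a signal of 1225. Next came peaks in an intron of Gug (Grunge, an Atrophin corepressor; 3L 8458180 to 8458486, signal 827), near CG13321 (2R 12958052 to 12958409, signal 825), in an intron of Kdm2 (a histone demethylase; 3R 9057359 to 9057792, signal 795) and near CG43131 (3R 5113129 to 5113421, signal 794).

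The 20 strongest promoter peaks were all in both replicate lists. The peak at px (FBgn0003175) spanned 2R 22514114 to 22514485, in an intron, with the summit 218 bp upstream of a px TSS and a signal of 1769. The peak between Art3 (an arginine methyltransferase gene) and mRpS10 (a mitochondrial ribosomal protein gene) spanned 3R 15229373 to 15229701 with a signal of 1228, its summit 124 bp upstream of Art3 and 133 bp upstream of mRpS10. Chro (Chromator, a chromatin architectural protein) had its summit in the 5′ UTR, 84 bp downstream of a TSS (3L 22878731 to 22879076, signal 1203). The Polycomb group gene ph-p (polyhomeotic proximal, FBgn0004861) held 2 of the 20 peaks, at X 2137185 to 2137526 in an intron (signal 1183) and at X 2137717 to 2138084 in the 5′ UTR (signal 1015). The remaining promoter peaks were nearest to CG14100, Ugalt, CG11309, Fkbp14, CG18549, RluA-1, MFS18, CG1888, CG1635, CG5611, Tina-1, CenG1A, mRpL41, Tcs5 and CG13390, with signals between 1283 and 881.

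Summits departed from the share of protein-coding TSSs on 3 of the 6 arms. Arm 3L held 729 summits (22.4% against 19.3% of TSSs, 1.16-fold, adjusted p = 4.0e-05), 2R held 562 (17.2% against 20.6%, 0.837-fold, adjusted p = 9.0e-06) and the small chromosome 4 held 12 (0.368% against 0.724%, 0.508-fold, adjusted p = 0.026) in exact binomial tests. Arms 2L, 3R and X did not pass. Against arm length in place of TSS share, 3L no longer passed and 2L and X did. The call on chromosome 4 was lost without replicate 1 (0.678-fold, exact adjusted p = 0.19) and among the 1000 strongest peaks (0.69-fold, adjusted p = 0.68), where 2L passed (1.19-fold, adjusted p = 0.014).

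Cytoplasmic ribosomal protein genes, which encode the core of the translation machinery, were bound more often than other genes, and no other list of the 19 passed as higher. Of 92 cytoplasmic ribosomal protein genes, 58 (63%, exact 95% interval 52.3 to 72.9) had an IDR summit within 500 bp of a TSS, against 13.3% of other protein-coding genes, a 4.76-fold excess (Fisher's exact test, two-sided, adjusted p = 7.2e-27 over 19 lists). Among the strongest were the peaks at RpL34b (3R 9401307 to 9401516, signal 368) and RpL7 (2L 10200938 to 10201186, signal 347). In all, 1897 of 13968 protein-coding genes (13.6%) had such a summit. Lists chosen as controls were bound less often: 0 of 179 chemoreceptor genes (exact adjusted p = 5.3e-11), which allows a share of up to 1.68%, and 0 of 70 cuticle protein genes (adjusted p = 0.00041), which allows up to 4.29%. Of 27 Jonah and trypsin protease genes 0 were bound, which allows up to 11.1% and did not pass (exact adjusted p = 0.12), although it did with a promoter window of 1000 bp (adjusted p = 0.0495). Among the 1000 strongest peaks the cuticle call was lost (exact adjusted p = 0.29).

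Genes of the Polycomb system did not pass as lists at promoters. None of the 8 Hox genes (lab, pb, Dfd, Scr, Antp, Ubx, abd-A and Abd-B), which set segment identity, had a promoter summit, which allows a share of up to 37.5% (exact adjusted p = 0.87). Of 88 other developmental regulators known as Polycomb targets, 7 were bound (7.95%, 0.584-fold, exact adjusted p = 0.33; 1.00-fold among the 1000 strongest peaks), among them ph-p, the cardiac regulator tin (3R 21378631 to 21378879, signal 475) and Poxm (3R 8334124 to 8334296, signal 329). Of 27 Polycomb group genes 7 were bound (25.9%, 1.91-fold, exact adjusted p = 0.198), led by ph-p, the H3K27 methyltransferase gene E(z) (3L 10637841 to 10638152, signal 422) and Spps itself, and of 27 trithorax group genes 4 were (14.8%, adjusted p = 0.87), led by brm (3L 15982885 to 15983153, signal 477), Rbbp5 (signal 135) and Bap60 (signal 119). The trithorax list stood at 1.09-fold, at 2.02-fold without replicate 1 (exact adjusted p = 0.156) and at 1.57-fold without replicate 2 (adjusted p = 0.41), but at 0.389-fold with the nearest TSS alone (adjusted p = 0.7), 0.818-fold among the 1000 strongest peaks and 0.786-fold against matched random lists. The Bap60 summit lay in the 5′ UTR of CG12096, and its peak ranked 7240 in replicate 1 and 3400 in replicate 2. The Rbbp5 peak ranked 1574 in replicate 1 and 3592 in replicate 2. Neither en nor inv had a promoter summit, and for ph-d the nearest summit lay 849 bp from a TSS. The Polycomb group genes passed without replicate 2 (2.63-fold, Fisher's exact test, adjusted p = 0.012) and when each summit was given to its nearest TSS alone (2.73-fold, adjusted p = 0.043).

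Other chromatin and growth genes did not pass at promoters either. Of 16 insulator and architectural protein genes 6 were bound (37.5%, 2.77-fold, exact adjusted p = 0.0702), led by Chro, Cp190 (3R 15275236 to 15275555, signal 572) and M1BP (signal 251). Of 32 cell cycle genes 9 were bound (28.1%, 2.08-fold, exact adjusted p = 0.103), led by CycE (signal 330), Dp (signal 245) and Cdk1 (signal 199). Both lists passed without replicate 2 (3.1-fold, exact adjusted p = 0.015, and 2.22-fold, adjusted p = 0.033), and the insulator list also among the 1000 strongest peaks (5.55-fold, adjusted p = 0.031) and with a promoter window of 1000 bp (2.79-fold, adjusted p = 0.027). The cell cycle list also passed with the nearest TSS alone (2.64-fold, exact adjusted p = 0.041). Of 73 mitochondrial ribosomal protein genes 17 were bound (23.3%, 1.72-fold, exact adjusted p = 0.091), led by mRpS10, mRpS23 (signal 947) and mRpL41 (signal 943). Against random lists matched on TSS number and gene length this list passed (2.92-fold, permutation adjusted p = 0.0025), and with each summit given to its nearest TSS alone it stood on the other side (0.718-fold, Fisher's exact test, adjusted p = 0.7). Of 32 proteasome subunit genes 7 were bound (21.9%, 1.61-fold, exact adjusted p = 0.33), led by Rpn3 (signal 234), Rpn6 (signal 134) and Rpn11 (signal 130). This list stood at 0.973-fold without replicate 1 and at 0.69-fold among the 1000 strongest peaks (exact adjusted p = 1 for each).

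Lists of signalling and tissue genes did not pass at promoters. Of 56 genes of the Notch, Wnt, Hedgehog, Dpp and EGFR pathways 11 were bound (19.6%, exact adjusted p = 0.33), led by the Notch target genes E(spl)m7-HLH (3R 26036485 to 26036835, signal 651), E(spl)mdelta-HLH (signal 414) and E(spl)m3-HLH (signal 402). Of 24 segmentation genes 2 were bound, ftz-f1 (signal 162) and bcd (signal 127), and of 8 Sp and KLF family genes 2 were, cbt (signal 464) and Spps. Mesoderm and muscle regulators had 3 of 18 bound (tin, htl and how), neural regulators and markers 2 of 20 (elav, signal 630, and pros, signal 128), endoderm and fat body regulators 1 of 8 (fkh, signal 204), and differentiated muscle and neuron effector genes 3 of 20 (sls, Tm1 and Act87E). Without replicate 2 the neural list went from 0.736-fold to 0.354-fold (exact adjusted p = 0.47) and the mesoderm list from 1.23-fold to 0.786-fold (adjusted p = 1). The signalling genes passed with a promoter window of 1000 bp (1.94-fold, exact adjusted p = 0.024). Whole embryos hold all cell types, so a summit at elav or tin does not place the binding in a tissue. The elav summit also lay in an intron of arg, and the cbt summit in an intron of ush.

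Counting summits anywhere in a gene or within 2 kb of it gave more lists above the rest. Of the signalling pathway genes 34 of 56 were then bound (60.7%, 2.35-fold, exact adjusted p = 2.7e-07), of the Polycomb group genes 14 of 27 (51.9%, 2-fold, adjusted p = 0.012), including Psc, Pc and Kdm2, of the trithorax group genes 13 of 27 (adjusted p = 0.029) and of the Hox genes 4 of 8 (Abd-B, Antp, Ubx and lab; adjusted p = 0.26). The insulator (2.17-fold, exact adjusted p = 0.026) and cell cycle lists (1.81-fold, adjusted p = 0.029) passed as well, and the ribosomal protein genes stood at 2.8-fold. Against random lists of the same TSS number and gene length, chosen after the data were seen, the signalling list still passed (1.75-fold, permutation adjusted p = 0.00095) and the Polycomb group (1.49-fold, adjusted p = 0.15) and trithorax group (1.32-fold, adjusted p = 0.36) lists did not. The insulator (permutation adjusted p = 0.096) and cell cycle lists (adjusted p = 0.12) lost their calls there, while the ribosomal protein genes (2.93-fold, adjusted p = 0.00095) and the mitochondrial ribosomal protein genes (2.28-fold, adjusted p = 0.00095) passed, each with the smallest p that the random lists can give.

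**Figure D3:**
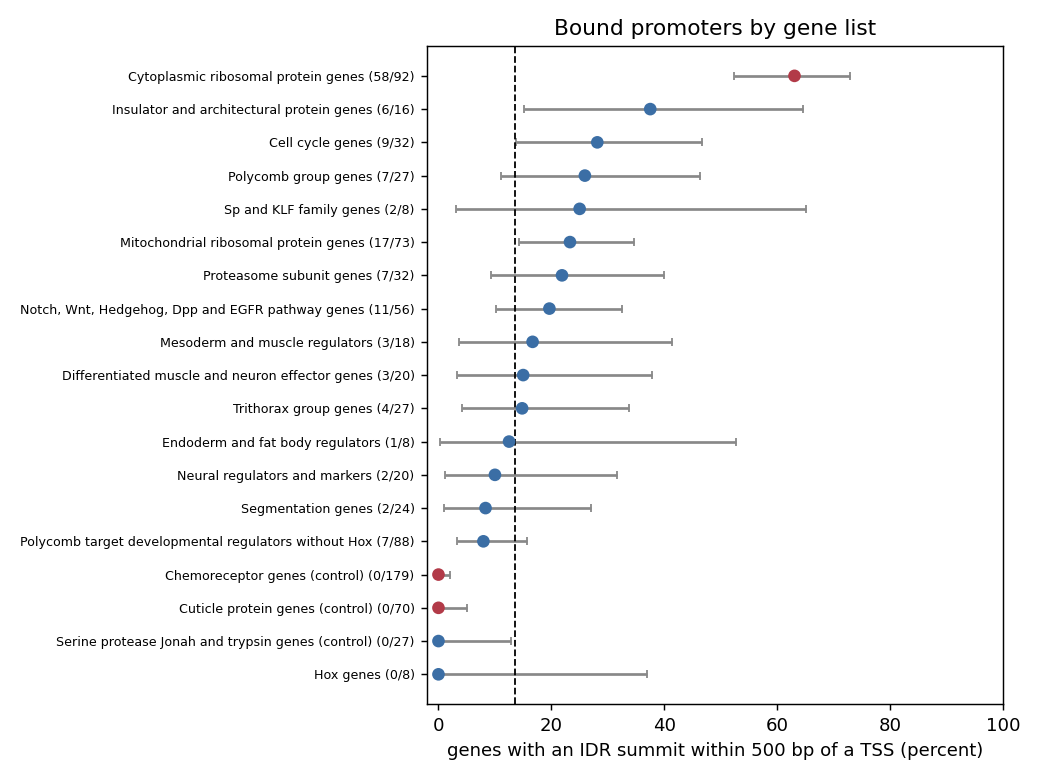
Each point is the percent of a list's genes with an IDR summit within 500 bp of a TSS, with its exact 95% interval and the bound and total gene numbers, and the dashed line marks the 13.6% of all protein-coding genes. Red points differ from other genes after Benjamini-Hochberg adjustment: the cytoplasmic ribosomal protein genes at 63%, and the chemoreceptor and cuticle genes at 0.

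No list passed as having stronger or weaker peaks than other bound genes. The 58 bound ribosomal protein genes had a median signal percentile of 51.5 among promoter peaks, and the 6 insulator genes 73.7, and none of the 11 lists with at least 3 bound genes passed against 10000 random sets of bound genes (lowest permutation adjusted p = 0.74, lowest unadjusted p = 0.15). Among the 1000 strongest peaks the mitochondrial ribosomal protein genes passed, at a median percentile of 87.9 (permutation, adjusted p = 0.042).

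The Hox complexes did not pass as holding more or fewer summits than random windows of their arms. The bithorax complex (3R 16656623 to 16972236) held 7 IDR summits against a mean of 7.78 in random windows of its length, the Antennapedia complex (3R 6661427 to 6999228) 10 against 8.48, and the en and inv locus (2R 11474465 to 11528210) 1 against 1.19, none of which passed (permutation adjusted p = 1 for each). The central 95% of random windows ran from 0 to 20 summits for the bithorax complex and from 0 to 21 for the Antennapedia complex, so only a large excess could have passed. The strongest summit of the bithorax complex lay in an intron of the noncoding RNA gene bxd (3R 16771740 to 16771857, signal 244), and that of the Antennapedia complex in an intron of Ama, an immunoglobulin superfamily gene (3R 6762899 to 6763232, signal 423). Introns of Antp held 3 summits, and 1 more within Antp lay in a noncoding exon where a noncoding RNA gene overlaps it.

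Sp/KLF sites were scarce under the summits. The core GGGCGKG occurred within 100 bp of 44 of 3260 summits (1.35%, exact 95% interval 0.982 to 1.81) and in 173 flanking windows 500 bp away (5.31%, 4.56 to 6.13), a 0.254-fold share (exact McNemar test, adjusted p = 2.1e-18 over 15 motifs). The relaxed Sp/KLF consensus (12.9% against 21.1%) and the GC box (2.48% against 8.47%) were also lower. Elements of housekeeping core promoters were higher over all summits: the DRE (TATCGATA) in 2.7% against 0.583% (4.63-fold), Motif 1 in 1.2% against 0.0613%, Motif 6 in 0.675% against 0.0613%, and the BEAF-32 core in 25.9% against 21.4%. The BEAF-32 core CGATA lies within the DRE sequence, so every window with a DRE counts for both. The TATA box was also higher (12.1% against 7.94%). Near a TSS a flank 500 bp away can lie outside the core promoter. The folds of core promoter elements against flanks therefore do not separate binding from position at promoters. The GAGA site (3.53% against 5.21%), the Zeste site, the GTGT repeat bound by Combgap (2.94% against 5.67%) and the CTCF core were lower, and the Pho, Zelda and Initiator sites did not pass. Among the 1000 strongest peaks the DRE (2.12-fold, exact adjusted p = 0.16), Motif 1 (adjusted p = 0.17), Motif 6 (5-fold, adjusted p = 0.27) and the BEAF-32 core (1.04-fold, adjusted p = 0.76) no longer passed. Without replicate 1 Motif 6 (2.43-fold) and the GAGA site (0.807-fold) lost their calls (exact adjusted p = 0.074 for each) and the Pho site passed as lower (0.786-fold, adjusted p = 0.0105), and the Zelda site passed as lower without either replicate (0.5-fold and 0.558-fold). With windows of 50 bp the BEAF-32 core (1.06-fold, exact adjusted p = 0.38) and the CTCF core (0.807-fold, adjusted p = 0.14) lost their calls, and the Pho site (0.719-fold, adjusted p = 0.0104) and the Initiator (0.837-fold, adjusted p = 0.037) passed as lower. The Pho site was also lower with windows of 200 bp (0.838-fold, exact adjusted p = 0.0039) and over 500 bp from a TSS (0.772-fold, adjusted p = 0.049). Within 500 bp of a TSS the Zelda site passed as lower (0.391-fold, exact adjusted p = 0.027), the CTCF core lost its call (0.813-fold, adjusted p = 0.19), and the GAGA site lost its call and stood on the other side (1.17-fold, adjusted p = 0.48). Over 500 bp from a TSS Motif 1 (1-fold, exact adjusted p = 1), Motif 6 (3-fold, adjusted p = 0.78), the DRE (0.6-fold, adjusted p = 0.84) and the BEAF-32 core (0.904-fold, adjusted p = 0.196) did not pass. Among values that kept their calls, Motif 1 stood at 19.5-fold and at 10-fold without replicate 1, and Motif 6 at 4.8-fold without replicate 2. The Sp/KLF core stood at 0.509-fold and the GC box at 0.605-fold with windows of 200 bp.

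The summits were AT-rich, and several motif directions turned when each window was set against its own shuffled sequence. Mean GC content was 30.5% in 51 bp at the summit and 43.6% at 500 bp upstream of it by coordinate. Against windows shuffled with their dinucleotide content kept, the Sp/KLF core stood at 1.47-fold (exact adjusted p = 0.16), the GAGA site at 5-fold (adjusted p = 9.6e-17), the GTGT repeat at 4.17-fold (adjusted p = 4.2e-12) and the TATA box at 0.893-fold (adjusted p = 0.12). The GC box (1.53-fold, exact adjusted p = 0.024), the Zeste site (1.54-fold, adjusted p = 2.8e-16) and the CTCF core (1.65-fold, adjusted p = 1.3e-05), lower than in flanks, passed as higher here. The DRE (11-fold, exact adjusted p = 5.5e-17), Motif 6 (5.5-fold), the BEAF-32 core (1.22-fold) and Motif 1 (39 windows against 0, at least 13-fold) stayed higher. This control changes both the base composition and the place of the control window. Shuffling also breaks up repeats such as GAGAGAG and GTGTGTGT, and no flanks were shuffled, so these folds alone show no enrichment at summits. In 51 bp windows the GAGA site stood at 0.491% and the GTGT repeat at 0.46% at the summit. At 1000 bp upstream by coordinate they stood at 0.859% and 1.35%. Against flanks, the GAGA site was higher at summits with windows of 200 bp (1.28-fold, exact adjusted p = 0.00046). In windows of 200 bp against shuffles, a pairing chosen after the data were seen, the Sp/KLF core was higher (1.92-fold, exact adjusted p = 2.4e-07). DRE sites lay at summits near a TSS: 85 of 1492 such windows held one, and 3 of 1768 windows farther from a TSS.

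**Figure D4:**
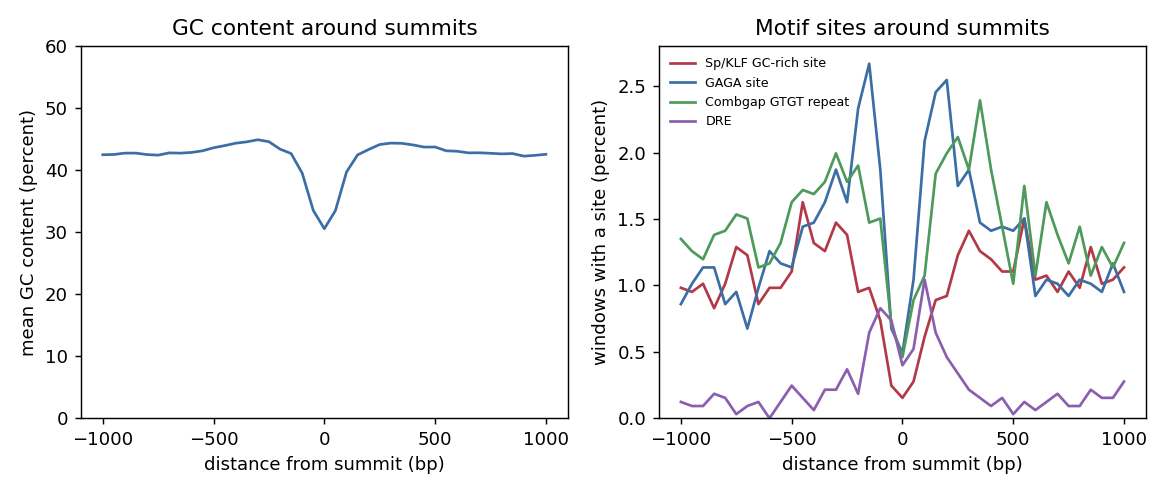
Left, mean GC content in 51 bp windows by distance from the summits of the 3260 IDR peaks, which falls to 30.5% at the summit. Right, the percent of those windows with an Sp/KLF, GAGA, GTGT or DRE site, where GAGA sites reach 2.67% at 150 bp before the summit and 0.491% at the summit.

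No motif passed as more frequent in the strongest peaks. Comparing the highest with the lowest signal quartile of 815 peaks each, Motif 1 (0.368% against 2.09%, adjusted p = 0.012), the BEAF-32 core (22.2% against 29.3%, adjusted p = 0.012), the CTCF core (4.54% against 8.47%, adjusted p = 0.012) and the Zeste site (19.4% against 25.4%, adjusted p = 0.016) were lower in the strongest quartile by Fisher's exact test. The Sp/KLF core had 10 sites against 12 (exact adjusted p = 0.96). Mean GC content in 101 bp at the summit was 28.5% in the strongest quartile and 34.2% in the weakest. No control for this difference was run, so its part in the lower calls is unknown. Without replicate 2 the CTCF core (0.655-fold, exact adjusted p = 0.15) and the Zeste site (0.786-fold, adjusted p = 0.056) lost their calls and the DRE passed as lower (0.393-fold, adjusted p = 0.043), while Motif 1 kept its call (0.111-fold). None of the 4 passed among the 1000 strongest peaks.

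Bound promoters carried GTGT and housekeeping elements more often than unbound ones, while the call on GAGA sites depended on the TSS chosen. For bound genes the TSS nearest to a summit was used, and for other genes the outermost (5′-most) TSS, so the TSS of a bound gene was chosen by the outcome. Within 200 bp of the TSS, the GAGA site occurred at 9.44% of 1897 bound and 6.27% of 12048 unbound genes (1.51-fold, Fisher's exact test, adjusted p = 3.4e-06), the GTGT repeat at 7.96% against 5.33% (1.49-fold), the DRE at 12.2% against 8.44% (1.44-fold), Motif 1 at 6.43% against 4.03% (1.6-fold) and Motif 6 at 3.27% against 1.9% (1.72-fold). The BEAF-32 core differed slightly (56.3% against 53.5%, exact adjusted p = 0.045) and lost its call when either replicate was left out. Promoters with a DRE count for this core too, and the core was not tested without them. The TATA box (16.5% against 21.6%, exact adjusted p = 1.5e-06) and the Initiator (34.1% against 43.1%, adjusted p = 1.4e-12) were less frequent at bound promoters, and the Sp/KLF core (4.43% against 4.64%, adjusted p = 0.78) and the GC box (10.4% against 9.8%, adjusted p = 0.54) did not pass. With windows of 500 bp the GC box passed as higher (1.12-fold, exact adjusted p = 0.0072). With the 1000 strongest peaks the DRE (0.905-fold, exact adjusted p = 0.58) and Motif 1 (0.602-fold, adjusted p = 0.098) lost their calls and stood on the other side, and the BEAF-32 core was lower (0.903-fold, adjusted p = 0.038). Motif 6 (1.38-fold, exact adjusted p = 0.38) and the Initiator (0.9-fold, adjusted p = 0.098) lost their calls there too, so of the elements above only the GAGA site and the GTGT repeat stayed higher. With the outermost TSS for every gene, an alternative chosen after the data were seen, the GAGA site no longer passed (1.21-fold, exact adjusted p = 0.057), while the GTGT repeat (1.25-fold, adjusted p = 0.049), the DRE (1.6-fold), Motif 1 (1.73-fold), Motif 6 (1.83-fold) and the BEAF-32 core (1.1-fold) stayed higher and the TATA box (0.783-fold) and the Initiator (0.78-fold) lower.

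Divergent promoters were bound more often than others. Of 4562 protein-coding genes with a divergent TSS within 1000 bp, 1102 (24.2%, exact 95% interval 22.9 to 25.4) had a promoter summit, against 795 of 9406 others (8.45%, 7.9 to 9.03), a 2.86-fold share (Fisher's exact test, p = 1.6e-133). A single summit between paired genes, as between Art3 and mRpS10, counts for both of them. With 1 gene counted per pair the share was 2.92-fold (Fisher's exact test, p = 3.3e-90). The gene kept could still be called bound by a summit at its partner's promoter. This count therefore does not remove the advantage of paired over single promoters. Giving each summit to its nearest TSS alone was not run here.

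The tagged gene itself held a promoter peak. The Spps promoter (FBgn0039169, 3R 24223445 to 24226934, minus strand) held a peak at 3R 24226771 to 24227146 with a signal of 161 and rank 1533 of 3260, its summit 25 bp upstream of the TSS in intergenic sequence. It ranked 1883 in replicate 1 and 1239 in replicate 2. A transgene can leave its own mark on such lists, and this was not tested. The peak, which also counts in the Polycomb group and the Sp and KLF lists, therefore does not by itself show binding at the gene. The gene and 20 kb to each side held 3 IDR summits against a mean of 1.07 in random windows (permutation p = 0.33). The strongest IDR peak of this stretch had a signal of 199 and rank 1094, above the promoter peak. In the longer lists the same stretch held 26 pooled summits against 9.45 (permutation p = 0.093), 20 against 9.65 in replicate 1 (p = 0.25) and 24 against 9.38 in replicate 2 (p = 0.12), none of which passed.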

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

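The count of peaks below the threshold and the test of signal quartiles were chosen after the main results had been seen. Below the IDR threshold, 8417 of the 26740 remaining pooled peaks (31.5%) had a summit within 100 bp in both replicate lists, a signal in data that the comparisons above do not use. After circular shifts the mean was 425.9 and the highest of 100 shifts 489. Both replicates also feed the pooled list, so this excess is not independent evidence of binding. Of these peaks 36.9% (35.9 to 37.9) lay at promoters, 2.72 times the share of sequence.

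IDR summits sat in AT-rich sequence, with 31.4% GC in 101 bp at the summit and 43.6% in flanks 500 bp away, a dip of 12.3 percentage points (SD 12.5 over peaks). Background calls near the threshold are argued against, since the dip was deeper in the highest than in the lowest signal quartile by 5.5 points (4.29 to 6.72, bootstrap). Windows as AT-rich as the summits lay at one 6.79 times (5.42 to 8.77) as often at promoters as in intergenic sequence, which restates the promoter excess of all summits (3.37-fold against 0.592-fold), so a library bias towards AT-rich DNA cannot be told apart from binding by this value. That bias, open chromatin at promoters and summit placement by the caller stay open. The design gives no second group, so no biological explanation was tested.

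Ribosomal protein promoters were bound at 63%. The tRNA genes were bound at 6.55% (3.99 to 10), under the 13.3% of other protein-coding genes. They were not matched to those genes on TSS number or gene length. Random genes matched that way to the mitochondrial ribosomal, cuticle and protease lists were bound at 7.99%, 9.38% and 5.92%, within the tRNA interval. Recovery at strongly occupied genes of every polymerase therefore stays open. A list of 39 other strongly transcribed housekeeping genes was bound at 41.0% (25.6 to 57.9), with the whole interval below the ribosomal share (Fisher's exact test, p = 0.022). This argues against an equal share at all strongly transcribed genes. Expression was not measured here and the 39 genes were not matched on it, so a share that rises with transcription stays open. That list was itself above other genes (exact p = 2.1e-05) and its interval overlaps the one of the ribosomal genes. Strong transcription may therefore account for part or all of the excess. No biological explanation other than strong transcription was tested.

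The Hox complexes did not pass as holding more IDR summits than random windows. Pooled peaks below the threshold were 1.13 times as dense in the bithorax complex as in random windows (permutation p = 0.86) and 1.02 times in the Antennapedia complex (p = 0.99), and the en and inv locus held 20 against a mean of 10.6 (p = 0.39). The central 95% of random windows ran from 0 to 134 such peaks against 68 in the bithorax complex and from 0 to 144 against 67 in the Antennapedia complex, so a bound of 1.5 times the mean, set beforehand, lay within their spread and decides nothing. Weaker sites left under the threshold stay open for all 3 loci, as does binding in a small share of the embryo's cells. No biological explanation was tested.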

How the results depend on the processing

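The combinations of gene body and matched lists and of 200 bp windows and shuffles, and the outermost TSS for promoter motifs, were chosen after seeing the data; the others were planned. No paired analysis was possible because there was only 1 group. Of 631 recomputed values for 108 results, 465 kept their direction and side of the threshold. Without turning direction, 30 lost their call and 32 gained one. A further 72 turned direction and 32 moved as values or counts. Some of the 72 also lost their call, among them the DRE and Motif 1 at promoters with only the strongest peaks. Others gained one, such as the Initiator with 200 bp windows and shuffles. More than 30 values therefore lost their call. The pooled top list is the IDR list and is not counted. Read depth is unknown, so its effect was not assessed. For every change below the cause was not tested.

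Replicate overlap was 71.2% in both directions with summits within 100 bp, 84.1% and 84.3% for the 1000 strongest peaks, 69.1% and 69.7% for lists of 6520, and 49.9% and 49.95% for all 30000.

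With the 1000 strongest IDR peaks, signal correlations were 0.88 (Pearson) and 0.791 (Spearman), and 632 genes were bound. Arm 3R stood at 0.975-fold, with 2 arms higher and 1 lower. Of the gene lists 2 were higher and 1 lower; Polycomb targets stood at 1.00, trithorax genes at 0.818, neural regulators at 1.11 and proteasome genes at 0.69. The ribosomal signal percentile was 32.6, with 1 list higher by signal, and the bithorax complex held 3 summits. At summits 1 motif was higher. By signal, ratios were 1.5 (Sp/KLF core), 1.11 (relaxed), 3 (GC box), 2.17 (Pho), 1.5 (GAGA), 0.717 (Initiator) and 1.08 (CTCF), with 0 lower. At promoters, ratios were 0.905 (DRE), 0.602 (Motif 1) and 0.903 (BEAF-32), with 2 motifs higher.

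Without either replicate in turn, the ranges were 0.989 to 1.04 for arm 3R, 1 to 2 for arms lower, 1 to 4 for lists higher, 0.973 to 1.77 for proteasome genes, 0.786 to 1.3 for mesoderm genes and 7 to 8 for bithorax summits. Signal percentiles ranged from 41.5 to 61.4 (signalling) and 46.7 to 57.9 (effectors). Motif ratios by signal ranged from 0.812 to 1.14 (Pho), 0.898 to 0.966 (Initiator) and 0.5 to 1 (Motif 6), and at promoters from 1.00 to 1.02 (relaxed Sp/KLF) and 0.999 to 1.05 (Zeste).

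With a promoter window of 250 bp, introns stood at 0.978, endoderm genes at 1.15 and effector genes at 0. With 1000 bp, effector genes stood at 0.955 and 3 lists were higher. With summits in the gene body or within 2 kb, 3627 genes were bound, 6 lists were higher, and Hox genes stood at 1.93, neural genes at 1.35 and endoderm genes at 2.41. With the nearest TSS only, 3 lists were higher, and trithorax genes stood at 0.389, neural genes at 1.05, endoderm genes at 1.31 and mitochondrial ribosomal genes at 0.718. Against matched lists, 2 lists were higher, and trithorax genes stood at 0.786 and effector genes at 0.641. With gene body and matched lists together, 3 were higher, and Hox genes stood at 1.13, neural genes at 1.11, endoderm genes at 1.61 and effector genes at 0.676.

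Against dinucleotide shuffles, 9 motifs were higher and 0 lower, at 1.47 (Sp/KLF core), 1.53 (GC box), 5 (GAGA), 1.54 (Zeste), 4.17 (GTGT), 0.893 (TATA), 1.05 (Initiator) and 1.65 (CTCF). With 200 bp windows and shuffles, 10 were higher and 0 lower, at 1.92 (Sp/KLF core), 1.87 (GC box), 7.9 (GAGA), 1.37 (Zeste), 7.19 (GTGT), 1.09 (Initiator) and 1.57 (CTCF). GAGA stood at 1.28 with 200 bp windows against flanks and at 1.17 for summits within 500 bp of a TSS. For summits farther away the DRE stood at 0.6 and BEAF-32 at 0.904, with 1 motif higher. At promoters, windows of 100 bp gave 1.04 (relaxed Sp/KLF), 1.08 (Pho) and 1.1 (CTCF), and windows of 500 bp gave 1.07 (Sp/KLF core), 1.02 (relaxed) and 1.02 (CTCF). With the outermost TSS the Zeste site stood at 0.999.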

Other observations

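All tests in this part were chosen after the main results were seen. The peaks used here were pooled peaks below the IDR threshold with a summit within 100 bp in both replicate lists. Both replicates feed the pooled list, so this match does not establish reproducibility. These peaks lay at promoters of cell cycle, signalling and proteasome genes more often than at other genes. Of 32 cell cycle genes 17 had such a peak within 500 bp of a TSS (53.1%, 2.32-fold, Fisher's exact test, adjusted p = 0.00096), of 56 signalling pathway genes 30 (53.6%, 2.34-fold, adjusted p = 1.0e-05) and of 32 proteasome subunit genes 14 (43.8%, 1.91-fold, adjusted p = 0.037). Cytoplasmic ribosomal protein genes did not pass there (24 of 92, 1.14-fold, exact adjusted p = 0.52), and 3 of 8 Hox genes had such a peak (adjusted p = 0.501). Of the 92 ribosomal genes, 58 already had an IDR summit in that window. IDR peaks were not counted here, so those genes could be counted only through a further summit. The missing call therefore does not show a lack of weaker binding. Chemoreceptor genes (5 of 179, exact adjusted p = 5.1e-13) and cuticle protein genes (3 of 70, 0.186-fold, adjusted p = 0.00026) were lower here too. With summits in the gene body or within 2 kb, against random lists matched on TSS number and gene length, the calls differed. Cytoplasmic ribosomal (52 of 92, 1.5-fold, permutation adjusted p = 0.0013), mitochondrial ribosomal (43 of 73, 1.94-fold, adjusted p = 0.0013, like the former from the smallest p that the random lists can give), cell cycle (25 of 32, 1.52-fold, adjusted p = 0.014) and proteasome genes (21 of 32, 1.69-fold, adjusted p = 0.016) passed, and the signalling genes did not (40 of 56, 1.22-fold, adjusted p = 0.13). Whether the IDR and weaker peaks differ in these lists was not tested.

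Apart from snRNA genes, noncoding genes were near a summit less often than the 13.6% of protein-coding genes. Within 500 bp of a TSS a summit lay at 153 of 3261 ncRNA genes (4.69%, 3.99 to 5.47), 10 of 269 snoRNA genes (3.72%, 1.8 to 6.73), 2 of 32 snRNA genes (6.25%, 0.766 to 20.8), 3 of 268 pseudogenes (1.12%, 0.231 to 3.24) and 0 of 99 rRNA genes (0 to 3.66). The snRNA interval includes 13.6%. Genes were not matched on TSS number or length, no test was run, and the share that random positions give was not computed. How well reads could be placed at each class is unknown, since the aligner and filters are not given. A low count therefore need not mean less binding.

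The GC dip at summits almost vanished below the threshold, from 12.3 percentage points in the IDR peaks to 1.71 in the remaining pooled peaks, 1.4 in replicate 1 and 1.58 in replicate 2.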
